A study of Mus musculus with 2 samples.

How the data were processed

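The material was rRNA-depleted total RNA from cells labelled megakaryocyte progenitor, of male C57BL/6J mice, in 2 libraries that the labels number as biological replicates 1 and 2. The labels name the ScriptSeq kit, a starting amount of 100 ng and a size range of 200 to 1000. How the cells were gated and sorted is not given in the sources used here. The labels name only an isolation of erythroid and megakaryocytic cells from bone marrow, in the title of a linked protocol that was not used here.

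Per the file headers, the authors deposited for each library a table of genes and a table of transcripts. The deposited expected counts are estimates per feature that share ambiguous reads between features, so they need not be whole, and 5.37% of genes in replicate 1 and 5.52% in replicate 2 had a value that was not exactly whole, with no tolerance. The deposited TPM values are expected counts divided by effective length and scaled to a fixed total over all features, per the file headers and the column totals, and a posterior mean TPM stands beside them. The deposited transcript tables also give the percent of a gene's TPM held by each of its transcripts. The build was mm10 and the annotation GENCODE M4, per the text file deposited with each sample. The quantification tool, its version, the aligner and the strand setting are not given in the sources used here, so antisense and overlapping genes cannot be separated with confidence. Signal tracks and alignments named in that text file were not used here.

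The tables held 43346 genes with an Ensembl identifier and 103639 transcripts, with 26248 numbered features, 96 spike-in sequences and 1 phiX sequence. Features without an Ensembl identifier were left out of the library sizes used for TMM scaling and of the gene summaries. Names, biotypes and coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 also denotes. By identifier without version, 42462 genes matched and 884 did not. The unmatched genes took 0.238% of the counts in replicate 1 and 0.214% in replicate 2. Ahsp and Snhg1 had no matching gene and were left out of their lists. Over all features, replicate 1 had 40797403 and replicate 2 had 70665381 expected counts. By these totals 3 counts, taken as the floor, equal 0.0735 and 0.0425 CPM (counts scaled by library size alone). The 10 highest genes took 47.3% and 49.9% of the TPM but 9.81% and 11.3% of the counts, so TPM levels depend on a few very short RNAs. For this reason TPM was also rescaled to the same total over protein-coding genes outside the mitochondrial genome, and expected counts were expressed as CPM after TMM scaling, without division by length.

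With 1 group of 2 libraries there was no test between groups and no p-value. The design was fixed before the data were examined. Levels were summarised as mean and SD. Each of 12 cell type lists and 23 other lists was described by its median log2(TPM + 1), with a pseudocount of 1, and by the percentile of that median among 10000 random lists of the same size from protein-coding genes. The lists were megakaryocyte, erythroid, granulocyte, monocyte and macrophage, dendritic cell, B cell, T and NK cell, mast cell and basophil, eosinophil, stem cell, endothelial and stromal genes, and transcription factors, platelet receptors, alpha granule cargo, granule biogenesis, cytoskeleton, cytokine receptors, thrombopoietin signalling, G1/S, G2/M, cytokinesis, glycolysis, haem and iron, eicosanoids, interferon response, immediate early genes, apoptosis, inherited platelet disorders, long non-coding RNAs, small structured RNAs, sex check, ribosomal proteins, the mitochondrial genome and histones. A gene counted as detected at a TPM of at least 1 in both libraries. A gene pair counted as apart when its mean difference in log2(TPM + 1) had the same sign in both libraries and exceeded 0.5 times the root of the summed squares of both genes' replicate spread, taken as the 95th percentile of the absolute difference between libraries over the 500 genes nearest in mean TPM. Between-library differences used genes with a mean TPM of at least 1, and list medians were set against 10000 random lists matched on mean expression, drawn for each member from its 200 nearest protein-coding genes. Transcript shares used transcription factors with a mean TPM of at least 5.

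The biological coefficient of variation came from expected counts rounded to whole numbers in edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr at a minimum count of 10 and an intercept-only model. DESeq2 1.42.0 gave alternative size factors. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counting intervals are exact Poisson intervals at 95%. The steps were tested on simulated data. On 13418 genes, coefficients of variation of 0.1, 0.2 and 0.4 were recovered as 0.101, 0.199 and 0.400, and as 0.150, 0.230 and 0.407 with 200 genes changed, so real differences between the libraries raise the estimate. On 9538 genes, 4.5% of 200 unchanged lists fell outside the 95% range of random lists, and 100% of 50 lists changed 2 fold were recovered in each direction. A 2 fold change is larger than any list median between libraries given below, and recovery of smaller changes was not tested.

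The genes named were set by a rule before the data were examined: the 20 genes of highest mean TPM, the 4 highest members and the lowest of each cell type list, the 4 highest and 2 lowest of each other list, all transcription factors, sex check genes and members of gene pairs, and the 10 largest differences between libraries in each direction among protein-coding genes with a mean TPM of at least 10. Exceptions are marked where they stand. The levels of some list and pair members, which stay in the counts of their lists and pairs, are not reported here. Alternatives fixed beforehand were the posterior mean TPM, rescaled TPM, TMM-scaled CPM, other pseudocounts, filters and thresholds, DESeq2 size factors, and each replicate left out. Chosen after the data were seen were list medians in CPM, in rescaled TPM, relative to the median gene and with the GC and length trend removed, the centred counts of genes, the count of detected members of each cell type list under the alternatives, a detection threshold of 10 expected counts, the rank of the granulocyte list, dominant transcripts among genes with several transcripts, the spread of the gap between list medians, and the criterion by which a list median counts as changed. A shift of 0.02 in a correlation was counted as a move, which was also set after the data were seen. Lists of early neutrophil precursor and late neutrophil genes were written after the cell type lists had been seen and before the values of their members were.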

Results

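Total RNA was sequenced from primary mouse cells that the labels call megakaryocyte progenitors, the bone marrow precursors that give rise to the platelet-producing megakaryocytes. The cells came from male C57BL/6J mice of 5 to 6 weeks, and 100 ng of RNA depleted of ribosomal RNA went into each library. The series held 1 group of 2 biological replicates, so the design gave no comparison between conditions. The labels name separate samples for the replicates but 1 donor record, and they do not say that the samples came from separate animals, so the spread given here may be partly technical. Depth was 40797403 expected counts in replicate 1 and 70665381 in replicate 2, which was 1.73 times as deep. Levels are TPM, the length-corrected abundance of transcripts, given as the mean ± SD of the 2 libraries (n = 2) unless the libraries are named singly. The median protein-coding gene was 0.35 higher in replicate 1 in log2(TPM + 1), but -0.01 in TMM-scaled CPM. The SDs of TPM include that shift, so a small SD does not by itself show equal levels after scaling. Of 43346 annotated genes, 9922 had a TPM of at least 1 in both libraries, among them 9166 of 21474 protein-coding genes, and 26027 genes had no count in either library. The Y-linked genes Eif2s3y (36.8 ± 8.35), Ddx3y (16.3 ± 4.43), Uty (8.39 ± 3.70) and Kdm5d (5.62 ± 1.71) were all detected, and Xist, the RNA of the inactive X chromosome, had 0 counts in both libraries.

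The most abundant lineage genes in the libraries labelled megakaryocyte progenitor were those of the granulocyte list, and most genes of the megakaryocyte list lay below a TPM of 1. Mpo, the myeloperoxidase of neutrophil primary granules, stood at 2297 ± 188 TPM and ranked 6 among protein-coding genes. Ctsg (1134 ± 121) and Elane (783 ± 12), serine proteases of the same granules, and S100a8 (1146 ± 378), a subunit of calprotectin, followed. All 18 members of the granulocyte list were detected, down to Mmp9, a gelatinase stored in the granules of later neutrophils, at 2.28 ± 0.806. The list's median TPM was 57.6 in replicate 1 and 83.6 in replicate 2, which ranked 1 among the 12 cell type lists in each library and lay at the percentile 100 of 10000 random protein-coding lists of the same size. On the mm10 build, Mpo (ENSMUSG00000009350.9) lies on chromosome 11 from 87793581 to 87804413, Elane (ENSMUSG00000020125.6) on chromosome 10 from 79886247 to 79888215, and Ctsg (ENSMUSG00000040314.1) on chromosome 14 from 56099881 to 56102574.

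Of the 22 megakaryocyte genes, 3 reached a TPM of 1 in both libraries. These were Itga2b (5.08 ± 2.31), the integrin chain CD41, Nbeal2 (4.32 ± 2.55), which is needed for alpha granules, and P2rx1 (1.20 ± 0.0778), an ATP-gated channel of platelets. Itgb3, the partner chain of Itga2b, stood at 1.28 ± 0.445. Pf4, encoding platelet factor 4, had 20 counts in each library (95% Poisson interval 12.2 to 30.9) and a TPM of 0.485 ± 0.262. Ppbp, a platelet chemokine, and Gp6, a collagen receptor, had 0 counts in both libraries. The set floor of 3 counts, which is not the interval used for Pf4, equals 0.0735 CPM (expected counts scaled by library size alone) in replicate 1 and 0.0425 in replicate 2. The median of log2(TPM + 1) over the list was 0.17 ± 0.11, at the percentile 33.8 of random protein-coding lists, and the list ranked 9 of 12 in both libraries. In TMM-scaled CPM, or in TPM rescaled to protein-coding genes, 6 of the 22 members reached 1 in both libraries, and replicate 1 alone had 5 members at a TPM of 1. Poisson intervals and floors cover counting error only. On mm10, Itga2b (ENSMUSG00000034664.9) lies on chromosome 11 from 102453297 to 102470122, and Pf4 (ENSMUSG00000029373.6) on chromosome 5 from 90772435 to 90773383.

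Lists of the other myeloid lineages and of stem cells lay between those extremes. Eosinophil genes ranked 2, with 7 of 8 detected and a median TPM of 3.53 and 4.89 in replicates 1 and 2. Prg2, encoding eosinophil major basic protein, stood at 53.1 ± 17.7 and Siglecf at 6.91 ± 1.03, while Il5ra, a chain of the interleukin 5 receptor, stood at 0.105 ± 0.134. Monocyte and macrophage genes ranked 3 (9 of 15 detected, medians 2.25 and 3.36), led by Ly6c2 (587 ± 66.2), the transcription factor Irf8 (48.1 ± 2.37) and the chemokine receptor Ccr2 (30.9 in replicate 1 and 29.2 in replicate 2), with the complement gene C1qb at 0.015 ± 0.0212. Erythroid genes ranked 4 (12 of 18 detected, medians 2.87 and 2.18), led by carbonic anhydrase 1, Car1 (69.0 ± 35.9), and the water channel Aqp1 (11.2 ± 5.83), while Alas2, the erythroid enzyme that starts haem synthesis, stood at 0.085 ± 0.00707. Stem cell and multipotent progenitor genes ranked 5 (8 of 15 detected), with medians of 3.99 in replicate 1 and 1.48 in replicate 2 and ranks of 2 and 6. Lmo2 (70.5 ± 22.1), Cd34 (69.1 ± 15.1), Cd48 (29.2 ± 2.52) and Kit (24.0 ± 7.39), the receptor of stem cell factor, were the highest of them and Hoxb5 (0.02 ± 0.0283) the lowest. The mast cell and basophil list ranked 6, with medians of 0.79 in replicate 1 (rank 6, percentile 54.4) and 2.92 in replicate 2 (rank 4, percentile 84.2). Of its members 5 of 10 were detected, namely Hdc (26.4 ± 6.25), which makes histamine, Cpa3 (12.7 ± 1.64), Mcpt8 (7.70 ± 0.820), Ms4a2 (5.10 ± 0.255) and Prss34 (3.60 ± 3.17), the last named after its values were seen.

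Lymphoid, dendritic, endothelial and stromal genes were mostly undetected. In each of these lists 1 or 2 members passed a TPM of 1 in both libraries. The dendritic cell list (1 of 9) held the cytokine receptor Flt3 at 5.67 ± 1.73. The T and NK cell list (1 of 15) held Nkg7, a cytotoxic granule protein, at 60.9 ± 1.27, while Lck stood at 1.10 ± 0.346. The B cell list (2 of 13) held Ighm at 40.2 ± 1.37 and Cd79b at 8.21 ± 1.01. The endothelial list (2 of 11) held Pecam1 at 11.3 ± 2.72 and Egfl7 at 6.77 ± 1.03, and the stromal and bone list (1 of 12) held Runx2 at 2.55 ± 0.933. Detection rose to 3 dendritic and 4 endothelial members in rescaled TPM or with replicate 1 alone, and to 4 and 5 in TMM-scaled CPM. In those settings it rose to 2 for the T and NK cell and the stromal lists, and the B cell count was unchanged. By the mean of the libraries their ranks were 7 for the dendritic, 8 for the endothelial, 10 for the T and NK cell, 11 for the B cell and 12 for the stromal list. In each library singly the B cell list ranked 10 and the T and NK cell list 11, tied with the stromal list in replicate 1. In replicate 1 the endothelial list ranked 7 and the dendritic list 8.

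**Figure D1:**
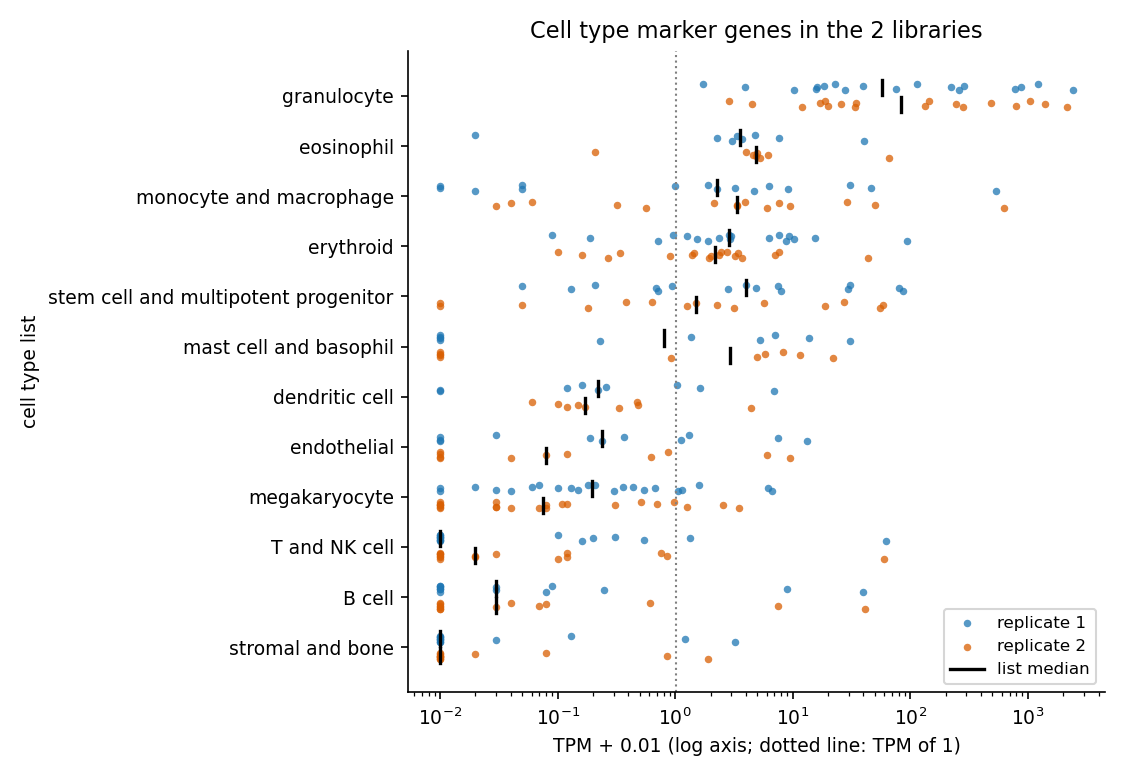
Each point is 1 marker gene in 1 library, placed by TPM + 0.01 on a logarithmic axis, with the 12 cell type lists ordered by the median level of their members and a black bar at each list's median in each library (replicate 1 blue, replicate 2 orange). The granulocyte medians stood at 57.6 and 83.6 TPM and the megakaryocyte medians at 0.185 and 0.065.

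Transcription factors of blood cell development were nearly all present, with Myb and Lmo2 highest. Of 26 listed factors, 25 reached a TPM of 1 in both libraries. Myb, a regulator of progenitor growth, stood at 144 ± 38.1 and Lmo2 at 70.5 ± 22.1, followed by Cbfb (46.2 ± 11.1), the partner subunit of the Runx factors. Nfe2 (36.8 ± 1.40) and Fli1 (28.7 ± 3.96), factors of the megakaryocyte lineage, stood near Spi1 (24.3 ± 0.856), encoding the myeloid factor PU.1. Ldb1 (26.3 ± 9.51), Gabpa (20.1 ± 6.12), Ikzf1 (19.7 ± 7.86), Etv6 (19.7 ± 4.74), Lyl1 (16.7 ± 1.09), Erg (14 ± 4.0) and Runx1 (13 ± 0.700) formed a middle group. Lower levels were found for Klf1 at 6.33 ± 4.14, Gata1 at 4.2 ± 2.92, Zfpm1 at 3.83 ± 1.53, Tal1 at 3.58 ± 1.87, Gfi1b at 3.23 ± 1.01 and Gata2 at 2.01 ± 1.09.

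Where a granulocytic gene was paired with a gene of the megakaryocyte or erythroid programme, the former was higher. Spi1 exceeded Gata1, the difference Gata1 minus Spi1 being -2.41 ± 0.81 in log2(TPM + 1), and Gfi1, a granulocyte factor, exceeded its homologue Gfi1b (-2.17 ± 0.28). Pf4 lay -10.60 ± 0.14 from Mpo. Fli1 exceeded the erythroid factor Klf1 by 2.14 ± 0.67. Pf4 was also below Hbb-bs, a beta globin gene (-0.87 ± 0.92). Among related genes, Tubb1, the tubulin of platelets, lay -7.98 ± 0.18 from the general Tubb5, the non-muscle myosin Myh9 exceeded Myh10 by 5.04 ± 0.12, Alas1 exceeded Alas2 by 6.81 ± 0.29, and Ptgs1 exceeded Ptgs2 by 3.15 ± 0.20. Ccnd3 exceeded Ccnd1 by 1.95 ± 0.30, Bcl2l1 lay -0.79 ± 0.17 from Bcl2, and P2ry12 lay -1.27 ± 0.55 from P2ry1. Itga2b exceeded Itgb3 by 1.38 ± 0.28, but in CPM, without division by length, that difference was -0.18, and with the posterior mean TPM the difference of 1.46 was not past the spread. In all, 15 of 18 pairs were further apart than the replicate spread at their levels, 7 with the first gene higher and 8 with the second. Not apart by that measure were Gata1 and Gata2 (0.71 ± 0.32, against a bound of 0.72) and Stat5a and Stat5b (-0.05 ± 0.24). Nor were the platelet receptor chains Gp1bb and Gp1ba (0.01 ± 0.07), which were both near 0 TPM. The replicate spread was taken without removing the shift of 0.35 between the libraries in the median protein-coding gene, so these bounds include it. Gata1 and Gata2 passed with the posterior mean TPM (0.73) and in rescaled TPM (0.89), and Stat5a and Stat5b passed in CPM (-0.60). On replicate 1 alone the Pf4 and Hbb-bs difference was -0.22 and on replicate 2 alone -1.52, and only the latter passed. With a pseudocount of 0.1 that call was lost as well (-1.63). The Bcl2l1 and Bcl2 call was lost on either replicate alone (-0.67 and -0.91). At the 99th percentile of the spread the calls for these 2 pairs and for Itga2b and Itgb3 were lost.

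**Figure D2:**
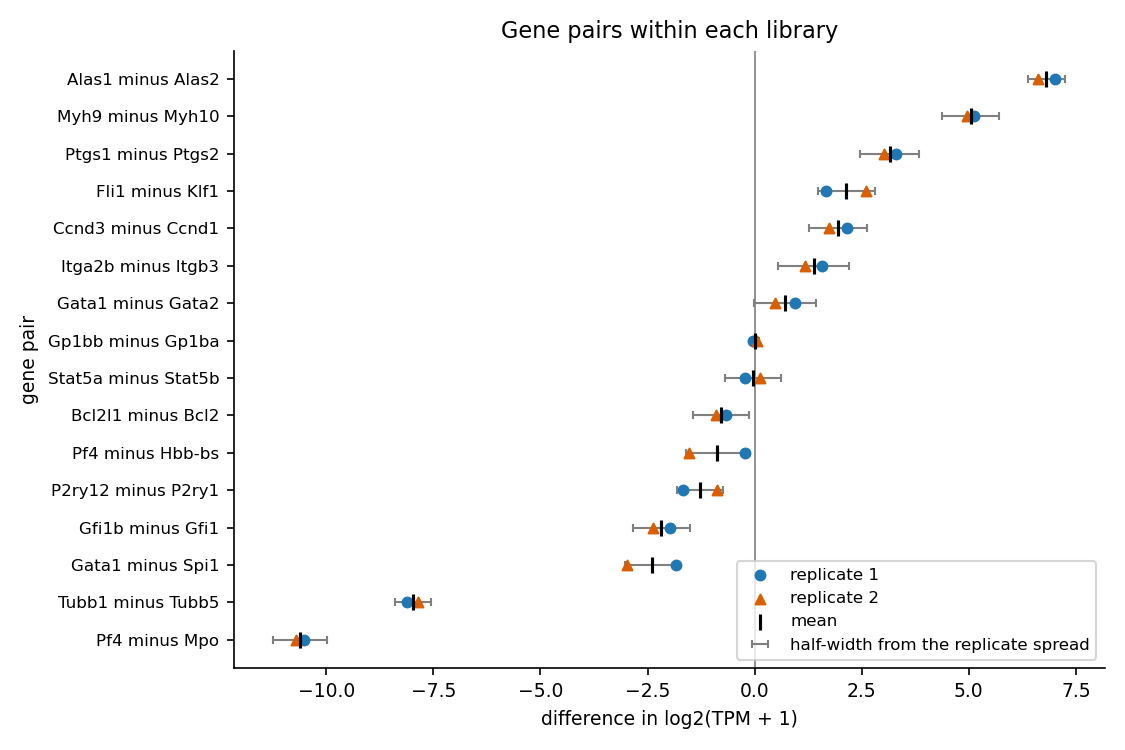
Differences in log2(TPM + 1) between the members of 16 of the fixed gene pairs, first minus second gene, for replicate 1 (circles) and replicate 2 (triangles), with the mean as a black bar and whiskers for the spread between libraries of genes of like level. Alas1 minus Alas2 (6.81) was the highest and Pf4 minus Mpo (-10.60) the lowest of the differences.

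For 17 of the transcription factors the mean TPM was at least 5, and their annotated transcripts were compared. In 12 of the 17, or 9 of the 14 with several annotated transcripts, 1 transcript held at least 50% of the gene's TPM in both libraries. Fli1-201 held 99.8% ± 0.304 of Fli1, Lmo2-208 93.4% ± 1.70 of Lmo2, and Myb-201 71.3% ± 4.35 of Myb. The highest transcript of Runx1, Runx1-201, held 36.4% ± 4.50, and in Cbfb and Ldb1 a different transcript was highest in each library. Transcripts of 1 gene share most exons, so these percentages are estimates from shared reads.

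Among genes of platelet function, components of secretion and of the cytoskeleton were mostly detected, and receptors and alpha granule cargo mostly were not. Of 22 platelet receptors 5 were detected, Itgb1 (38 ± 5.87), Fcer1g (36.9 ± 9.07), Itga6 (11.1 ± 3.80), Itga2b and P2rx1, and the list median was at the percentile 37.2 of random lists. Of 22 alpha granule cargo genes 8 were detected (percentile 55.3), with Srgn, the proteoglycan core serglycin, at 751 ± 24.7 and the coagulation factor gene F13a1 at 100.3 ± 0.12, ahead of Vegfa (14.3 ± 3.16) and Angpt1 (11.6 ± 7.45). Granule biogenesis and secretion genes were detected in 19 of 23 cases (percentile 99.7), led by Vamp8 (75.1 ± 14.6), Rab27a (46.0 ± 3.46) and Stxbp2 (36.2 ± 19.1). Of 21 cytoskeleton and proplatelet genes 18 were detected (percentile 100), led by Flna (136 ± 19), Cdc42 (134 ± 11.7), Tuba4a (103 ± 18.7) and Myh9 (80.6 ± 30.9). Tubb1 (0.045 ± 0.0636) and Myl9 (0 counts) were the lowest of that list. Among orthologues of genes of inherited platelet disorders 16 of 26 were detected (percentile 97.6), although 19 of the 26 also belong to other lists here. Cytokine receptors were detected in 15 of 19 cases (percentile 99.7), with Ifngr1 at 84.4 ± 19.4, Cxcr4 at 51.6 ± 8.78, Il11ra1 at 37.9 ± 2.64 and Ifnar2 at 32.1 ± 6.49. Thrombopoietin signalling genes were detected in 13 of 17 cases (percentile 99.8), led by Stat3 (22.3 ± 2.08) and Lyn (17.7 ± 2.69), with Socs2 at 0.135 ± 0.0778 and Cish at 0.075 ± 0.0354. The random lists came from all 21474 protein-coding genes, of which 9166 were detected. A high percentile therefore shows that a list was expressed, as the G1/S and glycolysis lists were (percentile 100 each). It does not show activity particular to platelets or to thrombopoietin.

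Genes of cell division and of glucose breakdown were nearly all detected. All 26 G1/S genes were present, with Pcna, the DNA polymerase clamp, at 156 ± 11.9, Cdk4 at 150 ± 16.8, and the replicative helicase genes Mcm7 at 114 ± 26.9 and Mcm6 at 114 ± 14. All 19 G2/M genes were present, led by Top2a (168 ± 37.5) and Mki67 (73.9 ± 20.7), as were 14 of 15 cytokinesis genes, led by Birc5 (53.5 ± 2.38), with Myh10 (1.45 ± 0.728) lowest. The 17 glycolysis genes were all detected, with Gapdh at 406 ± 34.2 and Pkm at 233 ± 29.2. Each of these 4 lists had its median at a percentile of at least 99.99. Haem and iron genes were detected in 17 of 19 cases (percentile 99.3), with the ferritin light chain Ftl1 at 233 ± 0.700 and Alas1 at 122 ± 23.5, and apoptosis genes in 11 of 12 (percentile 98.9), led by Casp8 (35.6 ± 7.63) and Mcl1 (35.5 ± 6.08).

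Immediate early and heat shock genes, which respond to cell stress and handling, were detected in 17 of 20 cases (percentile 99.7), with Hsp90aa1 at 405 ± 118, Jun at 37.4 ± 1.55 and Fos at 24.4 ± 3.54. Interferon response genes were detected in 4 of 13 (percentile 65.7), among them Bst2 (14.7 ± 2.40), Ifitm3 (14.5 ± 3.49) and Oas1a (3.15 ± 0.354). Eicosanoid genes were detected in 6 of 12 (percentile 72.5), led by Ptges3 (90.7 ± 21.6) and Alox5ap (75.8 ± 7.01), with the platelet lipoxygenase gene Alox12 at 0 counts.

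The content of RNA classes depended on the unit. Small nuclear RNAs held 32.5% ± 4.40 of the TPM but 0.911% ± 0.212 of the expected counts, and protein-coding genes outside the mitochondrion held 26.2% ± 3.90 of the TPM but 87.0% ± 0.984 of the counts. With the 13 mitochondrial genes, the protein-coding share was 27.0% ± 4.00 of the TPM (29.8% in replicate 1 and 24.2% in replicate 2) and 88.2% ± 0.919 of the counts. Rn7sk, the 7SK RNA that regulates transcription elongation, was the highest gene at 108009 ± 3051 TPM, ahead of the signal recognition particle RNAs Rn7s2 (61470 ± 1532) and Rn7s1 (61244 ± 1227), the snoRNA Gm22422 (48075 ± 576), the U2 RNA Rnu2-10 (39394 ± 2114) and Rpph1, the RNase P RNA (35013 ± 3639). The 20 highest genes were all short non-coding RNAs, and 15 of them were small nuclear RNAs, which exist in near-identical copies, so the level of any single copy is uncertain. Of the 8 small structured RNAs 5 were detected, the fifth being Rmrp (6996 ± 276), named after its values were seen, while Rny1 (7 and 4 counts) and Rny3 (47 and 35 counts) are listed at a TPM of 0. Of 14 long non-coding RNAs 9 were detected, led by Malat1 (578 ± 285) and Gas5 (452 ± 168). The lists of ribosomal proteins (79 of 82 detected, led by Rpl36a at 2388 ± 322) and replication-dependent histones (60 of 67, led by Hist2h2aa1 at 2444 ± 179) were both at the percentile 100, although histone copies share sequence. Of 37 mitochondrial genes 15 were detected, with mt-Co1 at 3001 ± 406 and mt-Atp8 at 3013 ± 565, which in CPM were at 9039 and 154, the effective length of mt-Atp8 being 23.6 and 21.5 bases in replicates 1 and 2, and the 22 transfer RNAs had no count. Genes annotated as ribosomal RNA outside the mitochondrion had 0% of the counts.

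**Figure D3:**
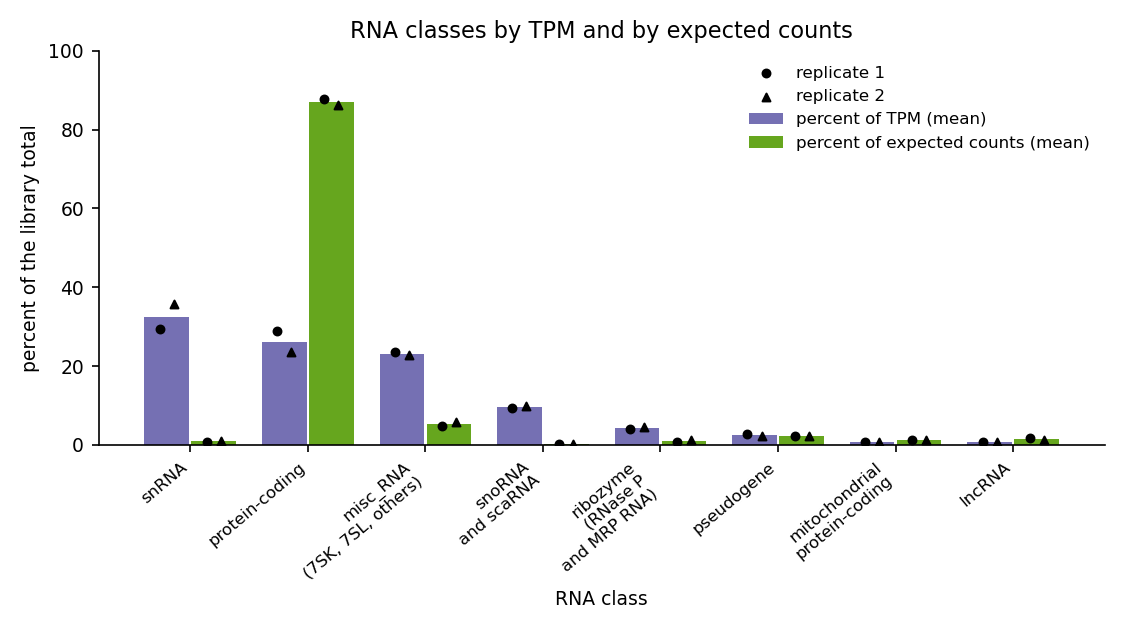
Bars give the mean percent of the library total held by each RNA class, by TPM (purple) and by expected counts (green), with each library as a symbol (circles replicate 1, triangles replicate 2). Protein-coding genes outside the mitochondrion held 26.2% of the TPM and 87.0% of the counts, and small nuclear RNAs 32.5% and 0.911%.

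The replicates correlated closely. Across 10973 genes log2(TPM + 1) had a Pearson correlation of 0.963 and a Spearman correlation of 0.955, genes not being independent replicates. The biological coefficient of variation shared over 13418 genes was 25.2%. Of 10847 genes with at least 100 counts in both libraries, 73.9% had a split of counts outside the 95% range of sampling alone, which describes 2 separate samples and tests no difference between them.

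Granulocyte, monocyte, eosinophil and immediate early genes were higher in replicate 2, and stem cell genes and erythroid genes other than globins were higher in replicate 1. These values compare 2 libraries of 1 group, with no replicate check. The median protein-coding gene was 0.35 higher in replicate 1 in log2(TPM + 1), so each list median is given relative to that shift, as replicate 1 minus replicate 2. The granulocyte median was -0.53 in TPM and -0.56 in TMM-scaled CPM, with 18 of 18 members lower in replicate 1 by CPM. S100a9, the other calprotectin subunit, stood at 287 TPM in replicate 1 and 490.1 in replicate 2, and Camp, encoding cathelicidin, at 75.7 and 132. They were among the 4 of 18 members lower in replicate 1 by at least 1 log2 unit in CPM. Mpo (-0.17) and Ctsg (-0.20) differed less in log2 CPM. In TPM both were higher in replicate 1, Mpo at 2430 and 2164 and Ctsg at 1219 and 1049. The monocyte median was -0.60 in TPM and -0.67 in CPM (10 of 10 members lower), the eosinophil median -0.81 and -0.95 (6 of 7), and the immediate early median -0.47 and -0.54 (17 of 19). The erythroid median was 0.25 in TPM and 0.33 in CPM (10 of 14 higher), with Car1 at 94.4 in replicate 1 and 43.6 in replicate 2. The 4 of these 14 that were lower in replicate 1 by CPM were globin genes, among them Hbb-bs at 0.94 and 2.73, and none of the 14 was higher there by 1 log2 unit in CPM. The stem cell median was 0.27 and 0.61 (8 of 10 higher), with Kit at 29.3 and 18.8. These 6 list medians lay beyond 95% of 10000 random lists matched on expression in either unit, in TPM rescaled to protein-coding genes, and after removal of the GC and length trend.

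Among the other lists, several calls depended on the unit or on the GC and length trend. Of 29 lists with enough members, 3 lay above and 8 below the 95% range of random lists in CPM, where 1.45 in all would by chance. That number holds for separate lists of genes drawn independently. Members of 1 list can move together, and some lists share members, so the excess over it cannot be weighed. Platelet receptors were 0.30 higher in replicate 1 in CPM (percentile 99), and 0.18 in TPM (96.9). Mast cell and basophil genes were at -0.33 (percentile 1.24) in CPM and -0.27 (3.26) in TPM. The alpha granule cargo median was -0.28 in CPM (percentile 1.11) and -0.29 in TPM (0.84). The transcription factor median was 0.13 in TPM (percentile 98.4), 0.09 in CPM (94.3) and 0.06 with the trend removed (87.1). Ribosomal protein genes were at -0.25 and histone genes at -0.23 in CPM, but at -0.06 (percentile 35.4) and -0.05 (47.1) once the GC and length trend was removed. The 4 expressed megakaryocyte members had a median of 0.24 in TPM and 0.19 in CPM (percentile 84.8).

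**Figure D4:**
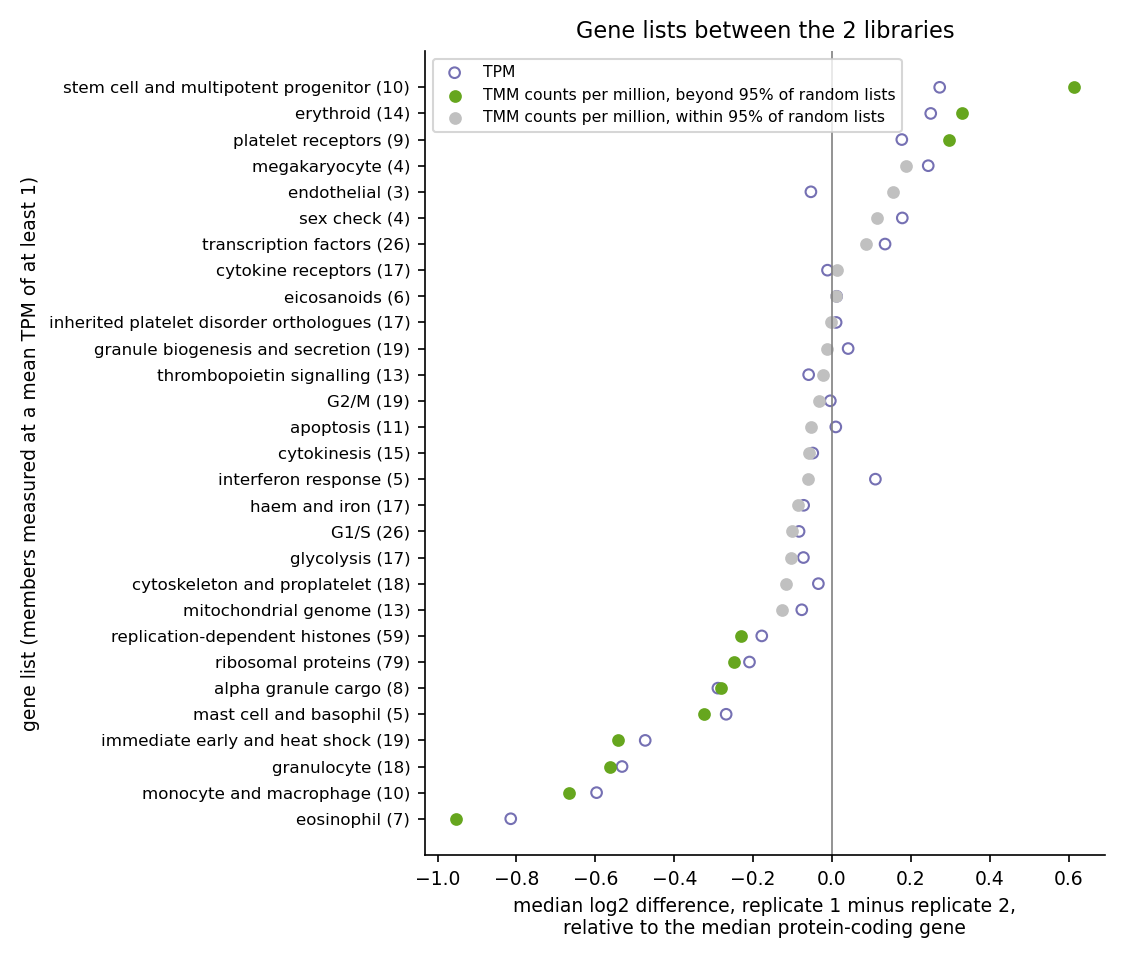
Median difference of each of 29 gene lists between the libraries, replicate 1 minus replicate 2 in log2 units and relative to the median protein-coding gene, in TPM (open circles) and in TMM-scaled CPM (filled, green where beyond 95% of random lists). Stem cell genes (0.61 in CPM) stood at the top and eosinophil genes (-0.95) at the bottom.

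Gene by gene, 461 of 10507 genes differed by at least 1 in log2(TPM + 1), 373 of them higher in replicate 1 and 88 in replicate 2. That split moved with the scaling, to 94 and 88 in CPM, 320 and 196 in rescaled TPM, and 137 and 175 with the median shift removed. Among protein-coding genes with a mean TPM of at least 10, Ccl3, a chemokine of activated myeloid cells, was higher in replicate 2 (11.4 and 29.0 TPM). Wfdc21, Lst1, Gng2 and Gm10273 were also among the 10 genes with the largest excess there, and Gm15446 too, although its difference had the other sign in CPM (0.24). Hist2h2aa2 (641 and 65.8), Hist1h2ad, Hist1h2ah and Hist2h2ab were higher in replicate 1, and Hist1h2ao (0.59 and 177) in replicate 2, but these histone copies are near-identical and their split is uncertain. The overlapping mitochondrial genes mt-Nd4l (47.1 and 4.11) and mt-Atp6 (15.7 and 59.9) are uncertain likewise. Isoc2b, Zfp101, Zfp26, Rnpc3 and B230307C23Rik were among the 10 most raised in replicate 1 by TPM, with differences of up to 1.69 that were 0.04 to 0.54 in CPM. Of these 20 genes, 13 differed by at least 1 log2 unit in the same direction in CPM. Of the 13, 5 were higher in replicate 1, all histone copies or mt-Nd4l, and 8 in replicate 2. Gm10273, Camp, S100a9, Wfdc21 and Lst1 reached that size in CPM only (TPM differences of -0.89 to -0.73). Among all 4059 protein-coding genes with a mean TPM of at least 10, 8 reached it in both units. Of these only Ccl3 was neither a histone nor a mitochondrial gene.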

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

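A few counts stood in a part of the tables that no comparison used. Numbered features without a gene identifier took 5 expected counts in replicate 2 and 0 in replicate 1. No biological explanation was tested, and a group of 2 libraries is too small for a test of 1 library against the rest.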

How the results depend on the processing

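The removal of the median shift, the detection threshold of 10 expected counts, dominant transcripts among genes with 2 or more transcripts, the settings for single gene lists and for counts of members, and the rank of the granulocyte list were chosen after the data were seen, the other settings beforehand. In 46 comparisons of a main value with an alternative the value stayed within its spread or within 1.5 times the count, and in 25 it moved. Detected genes numbered 6036 at a TPM of at least 5, since fewer genes can pass. The correlation was 0.925 with a pseudocount of 0.1 and 0.986 over all genes, most of them at 0, and the coefficient of variation was 50.7% with low counts included. Genes differing between libraries numbered 861 with a pseudocount of 0.1 (727 higher in replicate 1 and 134 in replicate 2), 135 at a mean TPM of at least 10 (110 and 25), where fewer genes were counted, and 182 in CPM, with 94 higher in replicate 1. With the median shift removed 137 and 175 were higher in replicates 1 and 2, and 196 were higher in replicate 2 in rescaled TPM. The megakaryocyte list median was 0.51 in rescaled TPM, 0.74 in CPM and -2.26 with a pseudocount of 0.1, each on its own scale, and the list ranked 8 with the posterior mean TPM, 8 in CPM and 11 by the mean over the list. Dominant transcripts numbered 5 at a share of 75% and 5 at a mean TPM of at least 20, both stricter by construction. The protein-coding share was 88.2% of expected counts and 36.5% with mitochondrial and small structured RNAs left out. Of single gene pairs, Itga2b and Itgb3 reversed to -0.18 in CPM. For the other changes the cause was not tested.

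With each replicate left out, detected genes ranged from 10176 to 10719 and the megakaryocyte median from 0.09 to 0.24. Dominant transcripts ranged from 13 to 14 and the protein-coding share from 24.2% to 29.8%, while the rank of the megakaryocyte list stayed at 9. The pairs apart fell to 13 with either replicate left out, from 15 with both. Among single lists, pairs and counts of members, 185 comparisons kept their value or call, 16 moved, 8 passed a threshold they had missed, 15 no longer passed and 1 reversed. Depth limits the lowest genes, such as Pf4 with 20 counts in each library. No paired analysis was possible because the series holds 1 group.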

Other observations

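The tests of gene length, of the megakaryocyte percentile, of the gate, of the erythroid and granulocyte gap, of the share of counts and of later-stage granulocyte genes were chosen after the results were seen, while the tests on the early and late neutrophil lists and on annotated length were set before their values were. Early neutrophil precursor genes, from a list with no member in any other list, were all detected (10 of 10), with a median TPM of 76.6 in replicate 1 and 64.2 in replicate 2. Plac8 stood at 982 ± 71.8, the lectin receptor Clec12a at 182 ± 9.40, Fcgr3 at 119 ± 5.18 and Igsf6 at 97.9 ± 18.3, and Cebpa, the factor that starts granulocyte commitment, at 7.54 ± 1.39. Genes of the late neutrophil list, which left out the later-stage members of the granulocyte list, were lower, with 7 of 10 detected and medians of 1.68 and 1.76. Itgam, an integrin of mature myeloid cells, stood at 8.76 ± 0.177, Trem1 at 3.84 ± 0.163, and Il1b at 0.17 ± 0.0849.

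In both libraries granulocyte genes were high (rank 1 of 12 lists) and megakaryocyte genes low (rank 9). Short length of the megakaryocyte genes was argued against. Their median effective length of 2269 bases in replicate 1 and 2112 in replicate 2 exceeded that of the granulocyte genes (855 and 852) by at least 1.31 ± 0.49 log2 units (SD over resampled members). Division by length favours shorter genes in TPM, so these lengths alone do not settle the contrast. In CPM, without that division, the megakaryocyte list ranked 8 of 12 and the granulocyte list ranked 1. Among members with an effective length of at least 1000 bases, 17 megakaryocyte genes had a median TPM of 0.29 and 0.07 in replicates 1 and 2. For 7 such granulocyte genes it was 18.5 and 18.8. A minority of granulocyte and monocyte cells among megakaryocyte progenitors stays open, since the megakaryocyte median, at the percentile 37.4 in replicate 1 and 31.1 in replicate 2, restates the low level, and excludes such a mix only on the premise that these progenitors carry the listed transcripts. Cells near the granulocyte-monocyte progenitor stage stay open. The early list exceeded the late list by at least 4.51 log2 units in each library, past the bound of 2. It exceeded 9 later-stage genes of the granulocyte list, among them S100a8, Camp and Ltf, by only 0.88 and 0.79 (their median TPM being 39.6 and 34.7), short of that bound. With both late sets together, 19 genes with a median TPM of 3.95 and 3.72, the excess was 3.92 and 3.71, past the bound. A sort gate that took granulocytic cells and a sample or label exchange cannot be told apart, since the granulocyte list ranked first in 2 of 2 libraries, the design holds 1 group, and the gate is not described in the sources used here.

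Erythroid genes other than globins, and stem cell genes, were higher in replicate 1 and granulocyte genes higher in replicate 2. Division by length was argued against as the whole cause, and so was the GC and length trend between the libraries, which held 8.68% of the variance across 9538 genes, since the gap between the erythroid and granulocyte medians was 0.89 ± 0.21 (SD over resampled members) in CPM without that division and 0.89 ± 0.21 once the trend was removed, above the bound of 0.3. Different mixes of cells in the samples stay open as a candidate explanation. The 9 late neutrophil genes, not used to find the pattern, had a median of -0.19 in log2 CPM, not taken relative to the median gene. Of these, 7 of 9 were lower in replicate 1, but at the percentile 9.01 of matched lists this missed the bound of 5. For the 7 members at a mean TPM of at least 1, the percentile depended on the unit. It was 8.7 in CPM, 4.56 in TPM, 3.69 in rescaled TPM and 18.2 with the trend removed. The early neutrophil precursor genes, with no bound set, had a median of -0.28 in log2 CPM, again not relative to the median gene. This lay at the percentile 1.06, or 1.96 with the trend removed, with 10 of 10 lower in replicate 1. A difference in handling or in the animals was not tested, and immediate early genes (-0.56 on that scale) moved with the granulocyte genes.

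Short structured RNAs held most of the TPM. Features with an effective length under 100 bases held 52.6% of the TPM in replicate 1 and 58.8% in replicate 2. With counts divided by annotated length they held 17.3% and 19.9% of the total, below the bound of 50%. These features were picked by their short effective length, so their share had to fall in that step. The values therefore give the size of the fall and do not test its cause. Division by a very small effective length stays a candidate cause. That such RNAs were most of the sequenced fragments was argued against, because the same features held 3.25% and 4.08% of the expected counts. This set leaves out Rn7sk and Rpph1, whose effective lengths were above 100 bases. Features under 150 bases, which take them in, held 67.3% and 73.8% of the TPM and 6.66% and 8.45% of the expected counts. Whether the share of short structured RNAs among molecules in the cells is near their share of TPM or of counts stays open. The size range of 200 to 1000 in the labels acts on such RNAs too.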
